A study of Homo sapiens with 20 samples.

How the data were processed

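Individual-nucleotide crosslinking and immunoprecipitation (iCLIP) of 3 RNA-binding proteins was measured in TREX FLP-In cells, a human embryonic kidney line that the labels call HEK293T in the protocol and HEK293 in the RNA-seq titles, and that carries a tetracycline-regulated integration site. The 16 iCLIP libraries comprised 4 for hnRNPA1, 6 for U2AF2 and 6 for SRSF1, shared equally between control cells and cells with inducible T7-tagged hnRNPA1. Polyadenylated RNA was sequenced from 2 control and 2 overexpression samples. Per the labels, cells were under selection for 3 days before use and under tetracycline for 24 h, iCLIP started from nuclear extracts, and RNA-seq started from whole-cell extracts. The groups were taken from the sample titles.

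Per the file headers, the authors mapped iCLIP reads to hg19 with TopHat, applied a repeat filter and called peaks in each library with CLIPper in its pre-mRNA mode. The labels name TopHat and Bowtie2 without versions, and no CLIPper version was stated. Each deposited peak carries coordinates, a strand, a p-value as CLIPper gave it, and a name that joins the gene ID, the peak number and the number of reads in the peak. The largest deposited p-value in each library was below 0.05. In 15 of the libraries every peak held at least 6 reads. U2AF2 overexpression replicate 3 listed peaks from 3 reads upwards and gave versioned gene IDs, so its peaks were called with another annotation or other settings. Peaks alike in interval, strand and read number made up at most 0.069% of the smaller library in any pair of replicates of 1 condition. Each library was therefore counted as a separate sample. The deposited RNA-seq table is the authors' MISO comparison of skipped exons: exon inclusion is a fraction per library, and the Bayes factor is a ratio per pair of libraries. It lists 251 events in which at least 1 of the 4 control and overexpression pairs had a difference of at least 0.33 and a Bayes factor of at least 5, a rule that was tested on the table and held for each event and pair. Differences were turned so that positive means higher inclusion with overexpression.

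Gene IDs were stripped of versions, and 17814 of 19362 (92.0%) matched the gene name table. Of these, 16207 had a symbol. Current names were matched by ID only, and coordinates stayed in hg19. The value per gene was the number of reads in its deposited peaks, summed per library and divided by a median-of-ratios size factor over genes with a peak in every library of the protein. A gene without a peak in a library counted as 0 there. Log2 values with a pseudocount of 1 were fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend), with the condition as the only term. Genes needed a peak in at least 50% of the libraries of the protein. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A gene called higher or lower is described as having risen or fallen. The difference between the U2AF2 and SRSF1 responses was tested as the interaction of protein and condition over 12 libraries. There a peak in at least 50% of the 12 libraries pooled was enough, so a gene could pass on U2AF2 peaks alone. Fitted values are given as mean log2 change ± SE and group values as mean ± SD of normalised reads.

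For 17 gene lists, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, and fry was run beside it. Adjustment covered the 47 list tests over the 3 proteins. Lists with under 5 measured members were not tested with camera. Members named by older symbols were matched through the synonym table where no current symbol matched. Shares of peaks overlapping the merged hnRNPA1 control peaks needed at least 1 nt on the same strand, and the chance level came from the same peaks moved by 1000 nt in either direction. A peak listed under several genes counted once. Reproducible sites were merged peaks found in at least 2 of the 3 libraries of 1 condition and in none of the other. Library-level shares and counts were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 and 0.3333 for 2 against 2. The split of events into higher and lower inclusion was compared with an exact two-sided binomial test that takes events as units. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

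The fits were tested on simulated data with the sizes of these libraries, known changes and an assumed spread between libraries. A minimum of 6 reads was set on the sum of each gene, whereas the deposited minimum acts on each peak. Peaks lost within a gene were therefore not simulated, nor was the minimum of 3 reads in U2AF2 overexpression replicate 3. Where 1 condition had far deeper libraries, unchanged genes near the minimum of 6 reads were called. With a peak in at least 50% of the libraries, 91.3% of the calls for U2AF2 and 96.3% for hnRNPA1 were false. For genes with a peak in every library these shares were 10.6% and 9.7%. Few genes were changed there: under the first filter, 93 by a log2 change of 1 and 91 by 2 among 11733 for U2AF2. For hnRNPA1 these were 88 and 82 among 10670. The false shares depend on these numbers, so they do not give the share of false calls among the real calls. For SRSF1 no unchanged gene was called under either filter, and 9% and 66.7% of the genes with a 4-fold change were recovered. Counts over all genes and of the main list results are therefore given under both filters, and the named genes lean on those with a peak in every library. The simulation cannot show how far peaks lost within a gene bias that set.

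The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took HNRNPA1, U2AF2 and SRSF1, the 10 largest changes in each direction among called genes with a symbol whose libraries of 1 condition all lay above those of the other, and the 3 members of each list with the smallest p. For events it took the 10 largest rises and the 10 largest falls. The same rule was applied to the genes with a peak in every library after the data were seen, and the text names a selection of the genes these rules gave; some others are not reported here. Sex-linked long non-coding RNAs were left out. The alternatives set beforehand were other scalings, filters, pseudocounts, peak sets and weights, the replicate number as a block, and each library left out. Thinning was added after seeing the data, in 2 forms, without calling peaks again. In the first, reads in peaks were drawn at random down to the total of the smallest library of the protein, and peaks left with under 6 reads were dropped. This left fewer reads in the libraries that had been deeper: 392252 to 520376 in U2AF2 overexpression libraries and 624909 to 702563 in U2AF2 control libraries. In the second, each library was thinned until the reads kept in peaks of at least 6 reads matched, which gave 702563 to 703284 reads in the U2AF2 libraries. Covered length still differed there, from 2101992 to 2570965 nt with overexpression and from 2675829 to 3415715 nt in control cells. Also added were peaks of at least 6 reads, peaks in genes shared by every library, combinations with the every-library filter, and other selections of events. Shares of U2AF2 peaks in Alu elements, near annotated 3' splice sites and at the 3' splice sites of the cassette exons were planned and not analysed here, because they need the hg19 sequence, an hg19 annotation or the exon boundaries of the events. The alternative with credible intervals was not run because the table used holds none. RNA levels per gene were not analysed here, so a change of iCLIP signal combines RNA level and crosslinking. The labels do not say whether replicates are separate cultures. Each p of a gene fit or library comparison therefore measures the spread between these samples, which may be technical. A p that takes events as units measures no spread between samples.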

Results

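The series asks how the level of hnRNPA1, an RNA-binding repressor of splicing, bears on where the splicing factors U2AF2 and SRSF1 contact RNA. U2AF2 recognises the polypyrimidine tract before 3' splice sites, and SRSF1 is a serine and arginine-rich (SR) protein that binds exonic enhancers. Deposited peaks were compared between control cells and cells overexpressing T7-tagged hnRNPA1, with 2 libraries per condition for hnRNPA1 and 3 per condition for U2AF2 and SRSF1. Depth differed between conditions. The hnRNPA1 libraries held 2973275 and 2508821 reads in peaks in control cells and 549365 and 575471 with overexpression. The U2AF2 control libraries held 702563, 783212 and 1158060 reads in peaks, and the overexpression libraries held 2701476, 2317615 and 3657197. The SRSF1 libraries were shallow, with 125082 to 173766 reads in control cells and 175293 to 329448 with overexpression.

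Peaks per library moved in opposite directions for hnRNPA1 and U2AF2. U2AF2 had 42310 ± 9985 peaks in control cells and 150683 ± 76652 with overexpression (SD, n = 3 each; ratio 3.56, exact permutation p = 0.1, the smallest this design allows). Overexpression replicate 3, which listed peaks from 3 reads upwards, held 239020 of these peaks. With peaks of at least 6 reads in every library the U2AF2 overexpression mean was 118803 ± 21818 and the ratio 2.81. Over all U2AF2 peaks, covered length had a ratio of 2.36 and reads in peaks a ratio of 3.28. The mean reads per interval lay between 20.3 and 21.7 in U2AF2 control libraries and between 15.2 and 24.1 with overexpression. For hnRNPA1 the mean was 128366 ± 7118 peaks in control cells and 43752 ± 824 with overexpression (n = 2 each; ratio 0.341, exact permutation p = 0.3333, the smallest this design allows). SRSF1 had 10202 ± 2227 and 13540 ± 4063 peaks (n = 3 each; ratio 1.33, exact permutation p = 0.3), a difference within the spread between libraries.

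**Figure D1:**
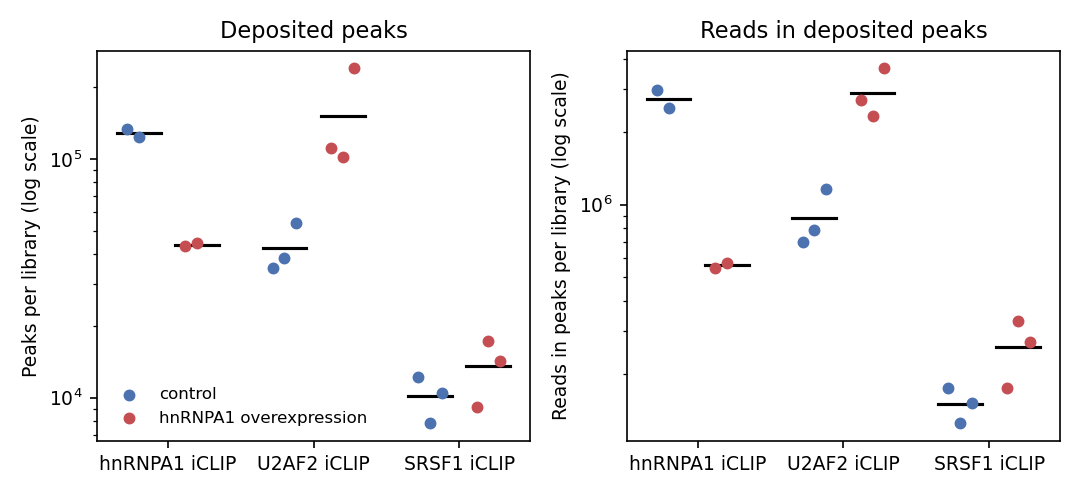
Number of deposited peaks (left) and reads in them (right) per iCLIP library, on log axes; points are libraries and lines are group means. U2AF2 overexpression libraries lie above all U2AF2 control libraries, hnRNPA1 overexpression libraries lie below both hnRNPA1 control libraries, and SRSF1 peak numbers overlap.

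U2AF2 signal fell on the transcripts of the 3 proteins studied. On HNRNPA1 itself (ENSG00000135486; hg19 chromosome 12, peaks from 54674572 to 54680513) U2AF2 signal went from 1264 ± 68.3 to 57.1 ± 20.5 normalised reads, a log2 change of -4.51 ± 0.29 (SE, n = 3 per condition, adjusted p = 0.000201). SRSF1 (ENSG00000136450; chromosome 17, 56078321 to 56083706) fell from 3629 ± 315 to 249 ± 140, and U2AF2 (ENSG00000063244; chromosome 19, 56166458 to 56186081) fell from 561 ± 59.6 to 207 ± 33.3, which did not pass with the number of peaks per gene. SF1, which binds the branch point beside U2AF2, fell by 4.63 on the log2 scale, and the splicing cofactors SON, SREK1 and SRRM1 changed by -4.27, -3.95 and -3.60. The nuclear long non-coding RNAs MALAT1 and NEAT1, which had the most signal among the named genes, fell from 38230 ± 5938 to 2680 ± 855 and from 13450 ± 1400 to 1515 ± 204.

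The steepest falls among genes with a U2AF2 peak in every library were in genes of other functions. SLC19A1, the reduced folate carrier (ENSG00000173638; chromosome 21, 46935058 to 46960719), went from 960 ± 165 to 9.22 ± 4.26 normalised reads (log2 change -6.64 ± 0.37, n = 3 per condition). CLPTM1L, GK (glycerol kinase), PTP4A1, CD164, RPL7A and the RNA helicase gene EIF4A2 followed, with log2 changes of -6.51, -6.26, -5.95, -5.89, -5.88 and -5.67. Rises were smaller in that set: MEGF9 3.17 ± 0.59, AGMO 3.01 ± 0.36, WDR62 2.79 ± 0.34, TUBD1 2.79 ± 0.25 and ZNF345 2.75 ± 0.38. ZNF37BP, ZNF33A, ZNF225, CAVIN1, AKR1A1 and DOCK10 had no called U2AF2 peak in any of 3 control libraries and means of 117, 101, 95.1, 97.9, 88.5 and 90.9 normalised reads with overexpression.

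**Figure D2:**
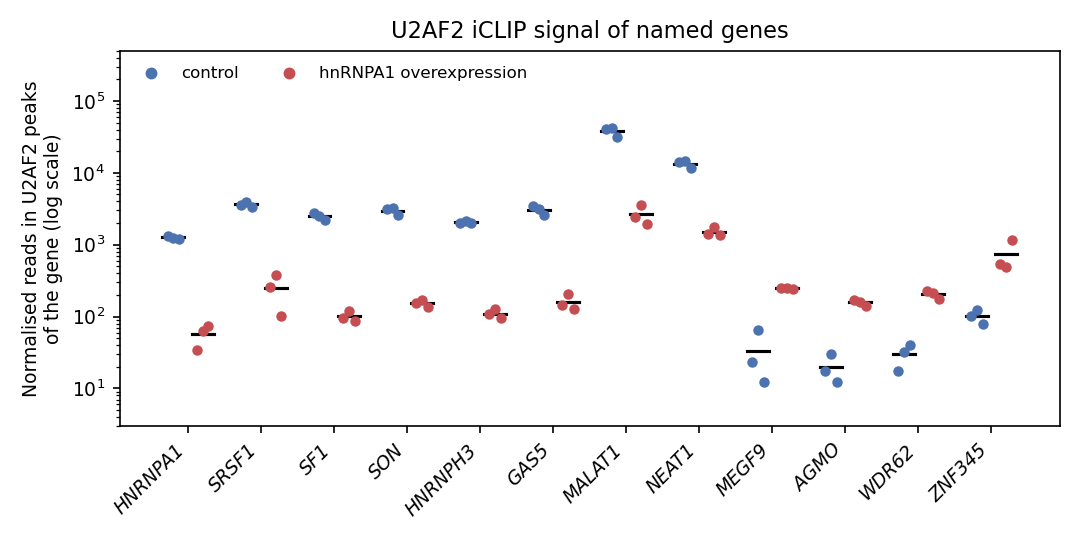
Normalised reads in U2AF2 peaks of 12 named genes, log axis; points are the 3 libraries per condition and lines are means. HNRNPA1, SRSF1, SF1, SON, HNRNPH3, GAS5, MALAT1 and NEAT1 were lower in all 3 overexpression libraries, and MEGF9, AGMO, WDR62 and ZNF345 were higher in all 3.

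By group, U2AF2 signal fell in 24 of 29 measured hnRNP family genes and rose in 0 (24 adjusted over the list alone), with HNRNPH3 at -4.21, HNRNPK at -4.02 and HNRNPR at -3.50. In the SR family list, which also holds the SR protein kinase gene SRPK1, 16 of 23 fell and 0 rose (16 adjusted over the list alone). Among snoRNA host genes 15 of 17 fell and 1 rose (15 and 1 adjusted over the list alone), including GAS5 at -4.27 and SNHG1 at -3.99. Cytoplasmic ribosomal protein genes fell in 43 of 80 and rose in 3 (46 and 3 adjusted over the list alone), and translation factor genes fell in 17 of 36 and rose in 1 (17 and 1 adjusted over the list alone), with EEF1A1 at -3.09. Camera adjusted p values were 6.16e-14, 1.3e-08, 4.38e-08, 1.81e-11 and 2.85e-06 in that order. With an estimated correlation the adjusted p was 0.157 for the hnRNP, SR, ribosomal protein and translation lists and 0.158 for snoRNA hosts, so no call held. With total reads as the scale, 22 of the 29 hnRNP family genes fell and 1 rose, and 13 of the 23 SR family genes fell and 2 rose. On that scale 12 of 17 snoRNA hosts fell and 1 rose, and 38 of 80 ribosomal protein genes fell and 9 rose. Translation factor genes fell in 17 of 36 and rose in 4. Among genes with a peak in every library, 22 of 27 hnRNP and 16 of 20 SR family genes fell and 0 rose. There 10 of 12 snoRNA hosts fell and 1 rose, 48 of 62 ribosomal protein genes fell and 2 rose, and 17 of 29 translation factor genes fell and 1 rose.

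Zinc finger (ZNF) genes, mostly transcription factors, went the other way: 109 of 322 rose and 20 fell (108 and 19 adjusted over the list alone), with a median log2 change of 1.42, or 0.33 with genes lacking peaks in 1 condition set to a floor. Among the 141 with a peak in every library 65 rose and 20 fell. For comparison, 3576 of all 13007 genes rose. In hnRNPA1 iCLIP, where the control libraries were deeper, 8 of 316 zinc finger genes rose and 110 fell (median -1.85). Depth and a gain of signal are therefore not told apart for this list. In U2AF2 the camera adjusted p was 0.0149, and adjusted p = 0.158 with an estimated correlation. ZNF207, which encodes a mitotic spindle protein, was an exception at -3.55. Further lists were 3' splice site and U2 factors (10 fell, 2 rose of 24; RBM39 at -3.10), other spliceosome factors (19 fell, 6 rose of 54), double-stranded RNA factors (9 fell, 5 rose of 22; SFPQ at -3.98), NMD factors (5 fell, 0 rose of 16; UPF3A at -1.87), cell cycle genes (11 fell, 4 rose of 50; CDK1 at -4.99, MKI67 at -3.93) and chromatin regulators (16 fell, 4 rose of 59; EZH2 at -3.51). Adjusted over the list alone these were 10 and 2, 19 and 6, 10 and 5, 5 and 0, 11 and 4, and 16 and 4. Their camera adjusted p values were 0.00346, 0.000584, 0.00524, 0.0224, 0.00429 and 0.00243, all down, and with an estimated correlation adjusted p was 0.282, 0.178, 0.157, 0.167, 0.157 and 0.195. With the number of peaks per gene none of the 6 was called (adjusted p = 0.0728, 0.0593, 0.102, 0.575, 0.269 and 0.756, the last in the up direction), nor were zinc finger genes (0.0728). The median of the 3' splice site list was 0.19, opposite in sign to its test, and with total reads as the scale the medians of all 6 lists were above 0. On that scale 15 chromatin regulators rose and 9 fell, 8 cell cycle genes rose and 8 fell, and 3 NMD factors rose and 2 fell. Other spliceosome factors rose in 12 and fell in 16, double-stranded RNA factors in 7 and 8, and 3' splice site and U2 factors in 4 and 10. With a peak in every library, the lists in their first order had 10 lower and 2 higher of 14, 21 and 5 of 39, 10 and 3 of 18, 6 and 0 of 10, 16 and 3 of 35, and 19 and 4 of 45.

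Among the abundant non-coding RNAs, U2AF2 signal fell in 4 of 6, MALAT1 and NEAT1 among them, and rose in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.00826 down, and adjusted p = 0.344 with an estimated correlation). DNA damage response genes went both ways, with 10 higher and 10 lower of 60 (9 and 8 adjusted over the list alone; adjusted p = 0.281), and with total reads as the scale 20 rose and 2 fell. FANCA, a Fanconi anaemia gene in that list, was at -1.46 and at 0.09 after quantile normalization. Oxidative phosphorylation genes had 7 higher and 9 lower of 62 (7 and 8 adjusted over the list alone; adjusted p = 0.281), with ATP5F1B at -3.21, and with total reads as the scale 14 rose and 4 fell. Histone genes had 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone; adjusted p = 0.192), and 0 higher and 5 lower after quantile normalization. Quantile normalization left 3 oxidative phosphorylation genes higher and 15 lower. With a peak in every library 10 DNA damage genes were higher and 15 lower of 46, and 5 oxidative phosphorylation genes were higher and 12 lower of 32. The medians of the DNA damage and oxidative phosphorylation lists were 0.34 and 0.65, opposite in sign to their tests. Of the 4 measured hematopoietic markers LYZ rose, 3 rose with total reads as the scale and 2 after quantile normalization, and this list was too small for camera.

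Over all genes, 5656 of 13007 changed in U2AF2 signal, 3576 higher and 2080 lower. Simulated libraries of these depths gave 712 false higher calls and 1 false lower call. Among the 6829 genes with a peak in every library 4048 changed, 1952 higher and 2096 lower, or 3293 and 1255 with total reads as the scale. The share called higher was 63.2%, against 80% with total reads as the scale and 48.2% in the every-library set. The median log2 change of all genes was 0.76, 1.49 with total reads as the scale and 0.18 after quantile normalization. The count was 3298 with the number of peaks per gene, and without overexpression replicates 1, 2 and 3 it was 2249, 2325 and 3005. Leaving out any of these turned the majority: 823 were higher and 1426 lower without replicate 1, 864 and 1461 without replicate 2, and 1238 and 1767 without replicate 3.

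**Figure D3:**
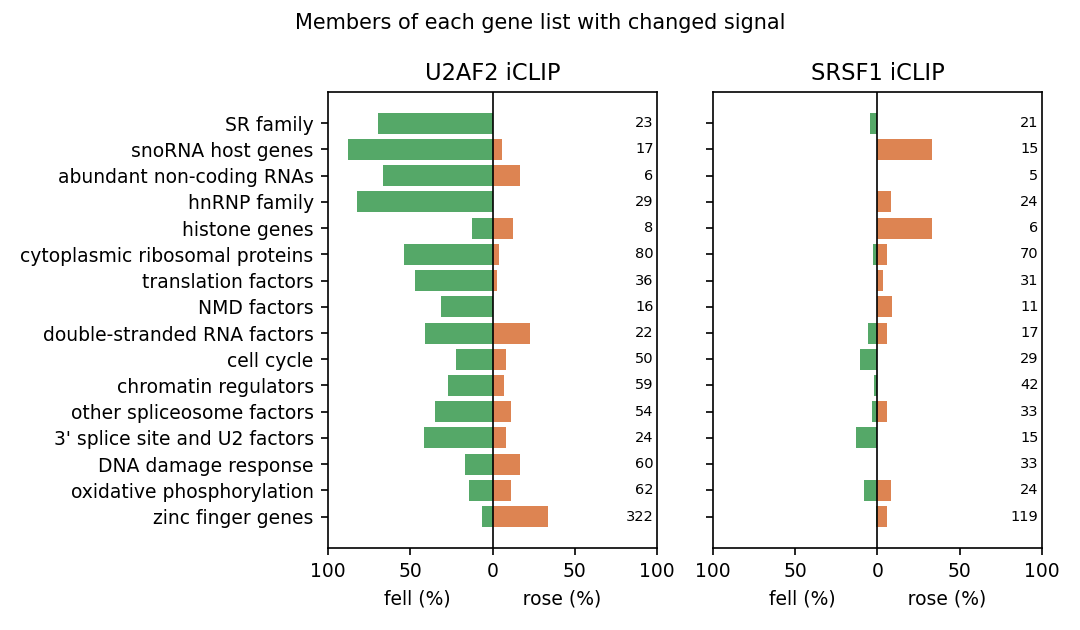
Share of the measured members of each gene list whose signal rose (right) or fell (left), for U2AF2 and SRSF1 iCLIP; numbers at the right edge are measured members. In U2AF2 the hnRNP family, SR family and snoRNA host genes mostly fell and zinc finger genes more often rose, and in SRSF1 few members passed.

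SRSF1 signal changed in fewer genes. It rose on LRP1B, a lipoprotein receptor gene (ENSG00000168702; chromosome 2, 141079571 to 142888522), from 12 ± 5.44 to 663 ± 328 normalised reads (log2 change 5.62 ± 0.48, n = 3 per condition, adjusted p = 0.0101). Rises also occurred on BIRC6 (3.10), DST (2.76), SNORD32A (2.63), the spliceosome kinase gene PRPF4B (2.63), RPSA (2.12), RPL13A (2.07), SNHG3 (2.0), EIF4A2 (1.53), GAS5 (1.47) and HNRNPH1 (0.88). With the number of peaks per gene EIF4A2, RPSA, RPL13A and SNORD32A turned, to -0.90, -0.33, -0.11 and -0.10, without passing. SNORD58C and TIPIN had no called peak in any of 3 control libraries and means of 161 and 51.1 with overexpression. It fell on SRPK1, the kinase that phosphorylates SR proteins (ENSG00000096063; chromosome 6, 35801750 to 35888320), from 153 ± 64.8 to 23.1 ± 7.55 (-2.65 ± 0.40), on U2AF1, the partner subunit of U2AF2 (-2.38), on SF1 (-2.10), ZNF529 (-3.11), E2F3 (-1.61) and MATR3 (-1.05). PTGES3 at -3.48 passed only with a peak in every library (adjusted p = 0.0186, against 0.0597).

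Of the SRSF1 lists, snoRNA host genes rose in 5 of 15 and fell in 0 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.314 with an estimated correlation). With total reads as the scale or quantile normalization 2 of the 15 rose, and with the number of peaks per gene the list was not called (adjusted p = 0.929). The SR family list also holds the kinase gene SRPK1, which was its 1 lower member of 21 (1 adjusted over the list alone). The list had a camera adjusted p of 0.00101 down, and adjusted p = 0.157 with an estimated correlation. Cell cycle genes fell in 3 of 29 (3 adjusted over the list alone), and ribosomal protein genes rose in 4 and fell in 2 of 70 (5 and 2 adjusted over the list alone), each with a camera adjusted p of 0.0237 down, and adjusted p = 0.225 and 0.638 with an estimated correlation. With the number of peaks per gene the cell cycle list was not called (adjusted p = 0.064). With total reads as the scale 5 ribosomal protein genes rose and 5 fell. With a peak in every library 4 of 12 snoRNA hosts and 4 of 42 ribosomal protein genes rose and 0 fell, and 1 of 16 SR family and 1 of 11 cell cycle genes fell. There the ribosomal list turned up, without a call (adjusted p = 0.933). The other SRSF1 lists tested were not called. HNRNPA1 at -0.06 ± 0.49, U2AF2 at -0.54 ± 0.39 and SRSF1 at -0.18 ± 0.28 did not pass. In all, 466 of 5598 genes changed, 357 higher and 109 lower, and 125 of 1845 with a peak in every library, 77 higher and 48 lower. With total reads as the scale the latter turned to 66 higher and 105 lower. The median log2 change of all genes was 0.36, against 0.17 with total reads as the scale and 0.08 after quantile normalization. Quantile normalization left 98 calls and no filter 29. Without control replicates 2 and 3 there were 67 and 24, and without overexpression replicates 1, 2 and 3 there were 15, 2 and 3. With every library thinned to equal reads kept in peaks, 181 were higher and 292 lower. Among genes with a peak in every library, leaving out control replicates 1, 2 and 3 gave 18, 196 and 85 calls, and leaving out overexpression replicates 2 and 3 gave 31 and 37.

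The U2AF2 and SRSF1 responses differed in 1173 of 8852 genes by the interaction test, with the U2AF2 change below the SRSF1 change in 910 and above it in 263. Only 5598 genes passed the filter for SRSF1 alone, so in many of the 8852 the difference can reflect the U2AF2 change alone. EIF4A2 fell in U2AF2 and rose in SRSF1 signal, a difference of -7.20 ± 0.54 on the log2 scale, although its SRSF1 change was -0.90 with the number of peaks per gene. GAS5 (-5.73), RPL13A (-5.78), HNRNPH1 (-5.75) and MALAT1 (-4.59) also differed. On HNRNPA1 the difference was -4.45 and on SRSF1 it was -3.86. Among the 1656 genes with a peak in every library 839 differed, 470 below and 369 above. With total reads as the scale 558 of 1360 were below, and the counts were 431 with the number of peaks per gene and 570, 621 and 673 without U2AF2 overexpression replicates 1, 2 and 3. They were 735 and 722 without U2AF2 control replicates 1 and 2.

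In the hnRNPA1 immunoprecipitation, signal rose on NEAT1 (ENSG00000245532; chromosome 11, 65190302 to 65212505) from 2820 ± 57.8 to 11630 ± 708 normalised reads, a log2 change of 2.04 ± 0.07 (SE, n = 2 per condition, adjusted p = 0.0023). MALAT1 rose by 1.16 ± 0.09, the related gene HNRNPA2B1 by 1.23 ± 0.05, HNRNPH1 by 0.74, EIF4G2 by 0.96, CCNB1 by 2.36 and the SR protein kinase genes SRPK2 and CLK1 by 1.26 and 1.68. The largest rises among genes with a peak in every library included CCDC138 (3.70 ± 0.26), LRRTM4 (3.10 ± 0.15) and NUP35 (3.05 ± 0.53). RUNX1, a transcription factor gene (ENSG00000159216; chromosome 21), fell from 319 ± 9.99 to 19.8 ± 4.14 (-3.96 ± 0.23), and POC1B and STAU2 changed by -3.09 and -2.0. ZNF273 and SLC7A11 had no called peak in either overexpression library, and SNORD58A and TMCO6 had none in either control library. HNRNPA1 at 0.20 ± 0.14, U2AF2 at 0.51 ± 0.15 and SRSF1 at 0.39 ± 0.09 did not pass (adjusted p = 0.355, 0.0888 and 0.0555). With quantile normalization MALAT1 was at -0.37.

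Of 12461 genes tested for hnRNPA1, 4792 changed, 537 higher and 4255 lower, with a median log2 change of -1.63, or -1.77 with total reads as the scale. Simulated libraries of these depths gave 4 false higher calls and 1545 false lower calls. Among the 5738 with a peak in every library 1023 changed, 545 higher and 478 lower, which turned to 415 and 661 with total reads as the scale. Quantile normalization left 5 calls, and leaving out control replicates 1 and 2 gave 320 and 345 calls. The majority then turned, with 243 higher and 77 lower without replicate 1 and 247 and 98 without replicate 2. Leaving out overexpression replicates 1 and 2 gave 7092 and 7704, and in the every-library set the counts without control replicates 1 and 2 were 547 and 616, and without overexpression replicates 1 and 2 they were 1514 and 1677. Against that median, 11 lists were called by camera, all up, and none held with an estimated correlation. Translation factors rose in 4 and fell in 1 of 35 (0 and 0 adjusted over the list alone; camera adjusted p = 2.07e-06, and adjusted p = 0.157 with an estimated correlation). Chromatin regulators rose in 9 and fell in 5 of 57 (8 and 5 adjusted over the list alone; camera adjusted p = 2.07e-06, and adjusted p = 0.157 with an estimated correlation), and the hnRNP family rose in 6 and fell in 4 of 30 (6 and 4 adjusted over the list alone; camera adjusted p = 0.0035, and adjusted p = 0.225 with an estimated correlation). With total reads as the scale 4 of the hnRNP family genes rose and 6 fell. The ribosomal protein list was called up with a median of -0.17 and with 0 members higher and 11 lower of 74 (camera adjusted p = 0.00982, and adjusted p = 0.178 with an estimated correlation). The double-stranded RNA, other spliceosome and SR family lists, also called up, had medians of -0.13, -0.03 and -0.01. With a peak in every library 11 chromatin regulators rose and 1 fell of 49, 3 hnRNP family genes rose and 0 fell of 25, 3 translation factors rose and 1 fell of 32, and 0 ribosomal protein genes rose and 4 fell of 51. In that set the ribosomal and double-stranded RNA lists turned down without a call (adjusted p = 0.883 and 0.933). With equal reads kept after thinning these 2 lists, the hnRNP and SR families and the 3' splice site list turned down, also without a call.

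Peaks of U2AF2 and SRSF1 were compared with hnRNPA1 control peaks to ask whether the proteins share sites. Of U2AF2 peaks, 43.6% ± 2.56 overlapped an hnRNPA1 control peak in control cells and 28.3% ± 5.19 with overexpression (SD, n = 3 each; difference -15.3 points, exact permutation p = 0.1, the smallest this design allows). Moved by 1000 nt, the same peaks overlapped in 16.2% ± 0.54 and 7.56% ± 0.98. The direction depended on the peaks taken: with every library thinned to equal reads kept in peaks the shares were 46.4% ± 2.17 and 57.1% ± 1.15, and with equal numbers of best-scored peaks 47.0% ± 2.87 and 64.0% ± 0.21. By share of reads they were 58.4% ± 2.51 and 60.1% ± 6.72. For SRSF1, 64.9% ± 8.52 and 67.5% ± 6.30 of peaks overlapped (exact permutation p = 0.7), a difference within the spread between libraries, against 14.1% ± 0.40 and 15.5% ± 0.18 for moved peaks. With equal reads kept the SRSF1 shares were 67.3% ± 10.5 and 77.8% ± 1.44 (exact permutation p = 0.1). Against hnRNPA1 overexpression peaks instead, the U2AF2 shares were 17.4% ± 1.64 and 5.47% ± 1.21, with 7.42% and 3.17% for moved peaks. The SRSF1 shares against these peaks were 32.9% ± 3.38 and 32.0% ± 3.79.

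**Figure D4:**
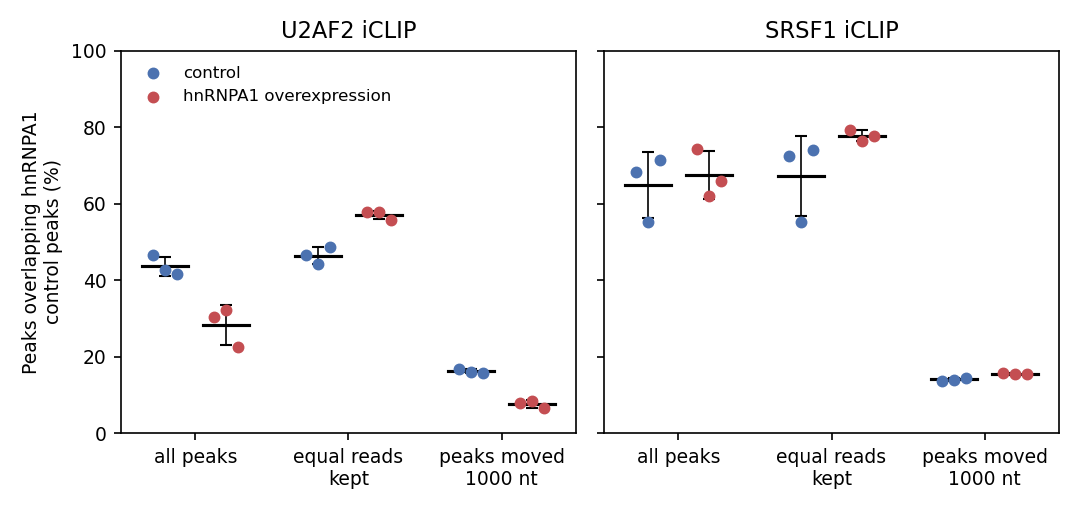
Percentage of U2AF2 and SRSF1 peaks that overlap hnRNPA1 control peaks per library, for all peaks, with equal reads kept after thinning, and for peaks moved by 1000 nt; points are libraries, lines are means and bars are SD (n = 3). For U2AF2 the overexpression libraries lie below the controls with all peaks (28.3% against 43.6%) and above them with equal reads kept (57.1% against 46.4%).

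At site level, 78068 reproducible U2AF2 sites were found with overexpression alone and 11329 in control cells alone, and 9035 were reproducible in both. With equal reads kept 17500 were found with overexpression alone and 12589 in control cells alone. For SRSF1 the counts were 2827 and 2023, with 3301 in both, and 1035 and 2126 with equal reads kept. Leaving out overexpression replicate 1, 2 or 3 left 1924, 1125 and 1185 SRSF1 sites with overexpression alone against 2279, 2569 and 2452 in control cells alone. Without control replicates 1 and 3 the latter were 657 and 847, and without control replicate 2 they were 1337. U2AF2 sites in control cells alone numbered 7221, 6279 and 5399 without control replicates 1, 2 and 3, and sites with overexpression alone numbered 43521 without overexpression replicate 3.

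Among the 251 skipped-exon events of the deposited comparison, inclusion was lower with overexpression in 155 and higher in 96 (exact binomial p = 0.000237). With 1 event per span, 142 were lower and 95 higher (exact binomial p = 0.00273). Neither p measures the spread between libraries, and 192 of the 251 events passed in only 1 of the 4 library pairs. The event in SRSF6, which encodes an SR protein (chromosome 20, 42087001 to 42088535), passed the authors' thresholds in all 4 library pairs. So did 1 event in MRPL55, a mitochondrial ribosomal protein gene (chromosome 1, 228295936 to 228297013). SRSF6 inclusion went from 0.675 ± 0.092 to 0.245 ± 0.007 and inclusion in that MRPL55 event from 0.785 ± 0.134 to 0.305 ± 0.021 (SD, n = 2 each). The other MRPL55 events listed on the same span were also lower and passed in 2 pairs each. Inclusion in WNK1, a kinase gene, was 0.81 in the 1 control library measured and 0.15 ± 0.042 with overexpression. NAP1L4 (0.62 ± 0.226 to 0.235 ± 0.163), HYI (0.555 ± 0.346 to 0.175 ± 0.049) and DPCD (0.465 ± 0.318 to 0.085 ± 0.035) were lower in both overexpression libraries. ZNF480 (0.6 ± 0.368 to 0.935 ± 0.021) and JMJD4 (0.51 ± 0.212 to 0.865 ± 0.092) were higher in both. The control libraries of these events lay far apart. Chance alone separates 2 against 2 libraries in 33.3% of cases, so separation shows little for a single event. ACAA1 inclusion was 0.3 in the 1 control library measured and 0.89 ± 0.014 with overexpression. The control libraries lay at least 0.33 apart in 77 of 174 events measured in both, and the overexpression libraries in 34 of 241. Without control replicate 2 the split was 57 lower and 47 higher (p = 0.378, exact binomial). The depth of the RNA-seq libraries is unknown from the table, and the labels leave open whether the RNA-seq control cells were the parental or the uninduced line.

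**Figure D5:**
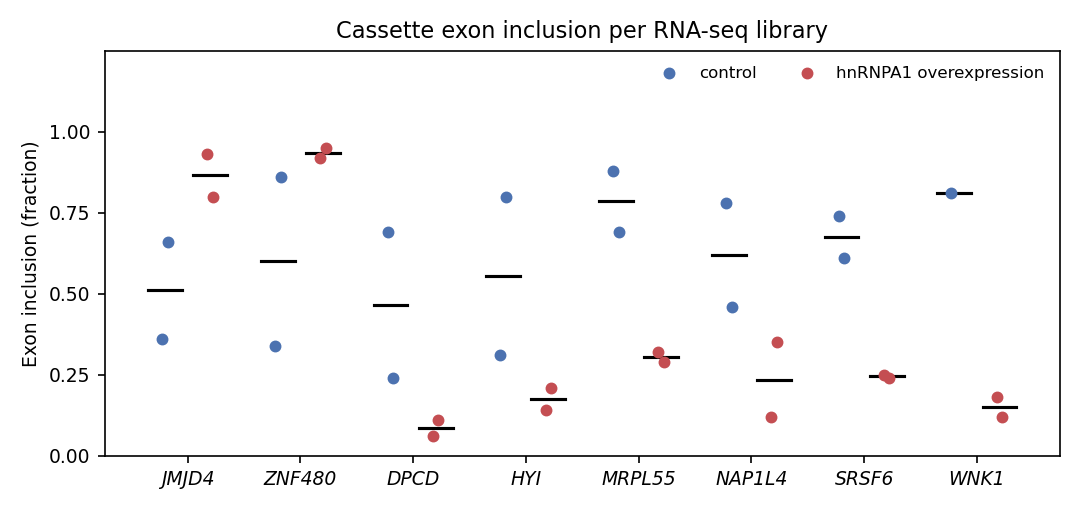
Inclusion fraction of the cassette exon of 8 named events per RNA-seq library; points are libraries (n = 2 per condition, 1 control for WNK1) and lines are means. SRSF6 and MRPL55 lie at 0.675 and 0.785 in control cells and at 0.245 and 0.305 with overexpression.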

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

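The tests after thinning, on thinned copies, on unscaled reads, on the SRSF1 change of genes called for U2AF2, without overexpression replicate 3 in the overlap and in the every-library set, and within genes shared by every library were chosen only after the result was seen.

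The response of U2AF2 signal differed from that of SRSF1 signal in 1173 genes by the interaction test, which also took genes with too few SRSF1 peaks for the SRSF1 fit. The values below are the U2AF2 log2 change minus the SRSF1 log2 change. Among genes whose SRSF1 signal rose, the difference was -7.20 for EIF4A2, -6.98 for LRP1B, -6.81 for SNORD32A, -6.54 for PRPF4B, -5.78 for RPL13A, -5.75 for HNRNPH1, -5.73 for GAS5, -4.76 for DST, -4.0 for RPSA, -2.99 for BIRC6 and -2.59 for SNHG3. Among genes whose U2AF2 signal fell, it was -6.17 for SLC19A1, -5.19 for RPL7A, -4.59 for MALAT1, -4.57 for SNHG1, -4.50 for EZH2, -4.45 for HNRNPA1, -4.45 for MKI67, -4.36 for SREK1, -4.32 for ATP5F1B, -4.02 for NEAT1, -3.93 for HNRNPK, -3.86 for SRSF1, -3.82 for CDK1, -3.77 for RBM39 and -3.48 for HNRNPH3. It was -3.26 for SFPQ, -2.96 for SON, -2.52 for SF1, -2.49 for UPF3A, -2.42 for HNRNPR, -2.21 for SRRM1, -2.04 for ZNF207 and -1.05 for FANCA. For the zinc finger genes ZNF345 and ZNF529 it was 2.65 and 3.13, and for E2F3 it was 2.42. Of 100 splits of the libraries, 1, the real one, gave as many genes. Most splits exchanged U2AF2 labels and so removed the U2AF2 change itself, so this share excludes chance labels only for both proteins together. The drawn splits that kept the U2AF2 labels and exchanged SRSF1 libraries gave 473 to 914 genes. They are too few to exclude chance labels for SRSF1. Most of such a count can arise while SRSF1 libraries carry exchanged labels.

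U2AF2 signal changed in 5656 genes while the overexpression libraries were deeper. To see what a depth gap does alone, libraries were set against copies of themselves thinned by the depth ratio of the conditions. The 2080 genes called lower moved by 0.22 in control and 0.64 in overexpression libraries, against -2.34 between the conditions, which argues against depth as the cause of the falls, as far as thinning without new peak calling stands for it. Only 486 of them (23.4%) had fewer reads without scaling in every overexpression library than in every control library. These included HNRNPA1 (at most 234 against at least 452 reads), SF1 (275 against 931) and MALAT1 (6985 against 13901), but not U2AF2, UPF3A, FANCA or EEF1A1. By the bounds written for that test so low a share is what depth as the cause would give, so it adds nothing against depth. The other falls were not separated between conditions before scaling. Thinned across conditions, the median of the 2080 genes was -3.89 with equal reads drawn and -3.47 with equal reads kept. Dropping weak peaks can itself deepen a fall there. For genes called higher depth and a gain of signal cannot be told apart: against 2.27, their median was 0.88 and 1.20 in these thinnings, with genes lacking a value at 0. A depth gap alone moved them by 1.05 in control libraries (1698 of 3576 with a value) and by -0.10 in overexpression libraries. Without overexpression replicate 3, 2858 of the 5656 called genes (50.5%) kept call and direction, with 4016 of them still tested. Without replicates 1 and 2, 2244 and 2316 kept them. Among genes with a peak in every library 85.0% did without replicate 3, which argues against its peak calling as the cause in that set. A changed RNA level was taken to move SRSF1 signal too. Of 2096 genes called lower for U2AF2 with a peak in every library, 636 also had an SRSF1 peak in every library. Their median SRSF1 change was 0.04, against -2.15 for U2AF2. Of 1952 called higher, 561 had, with a median SRSF1 change of 0.04, against 1.24. This argues against RNA level as the general cause among these genes only. The set leaves out genes whose SRSF1 signal was lost or newly gained, so it favours small SRSF1 changes. RNA level stays open for single genes and for genes outside that set. An effect of hnRNPA1 on U2AF2 binding stays open and untested.

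Some genes moved the same way in several immunoprecipitations, such as SF1, which fell in U2AF2 and in SRSF1 signal. Across 4403 genes the U2AF2 and hnRNPA1 log2 changes had a Spearman rho of -0.201, the sign that opposite depth gaps predict. Opposite effects on binding may give the same sign, and genes are not independent replicates. Between U2AF2 and SRSF1 changes rho was -0.005 over 1656 genes with 50.4% of signs alike. This was short of the value above 0.1 set for a shared difference in RNA level as the general cause. It was also not clearly under 0, the bound set against it, so the relation decides nothing about that difference. For single genes such as SF1 that difference stays open.

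The share of U2AF2 peaks overlapping hnRNPA1 control peaks was lower with overexpression by the count of peaks. With equal reads kept the difference was 10.644 points in the other direction, so deeper peak lists are a candidate explanation for the lower share. Thinning keeps the stronger peaks of deeper libraries and left their covered length shorter, so the higher share is not a finding either, and the 17.883 points with equal reads drawn, which left the overexpression libraries shallower, decide nothing. Without overexpression replicate 3 it was -12.345, and within genes that had a peak in every library it was -15.396, which argues against the peak calling of that library and against other genes as the cause. An effect of hnRNPA1 on which sites U2AF2 holds stays open, with a direction that depends on how depth is treated.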

How the results depend on the processing

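The alternatives with thinning, peaks of at least 6 reads, shared genes, combinations with the every-library filter and further event selections were chosen after seeing the data. Of 2230 alternative values of named genes 1953 kept direction and call, 224 lost the call, 29 gained it and 24 changed direction. Unless stated otherwise the cause was not tested.

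For hnRNPA1 the count of changed genes was 5 with quantile normalization, 1023 with a peak in every library (fewer genes tested), 1076 and 1088 there with total reads or the replicate block, 2758 with equal numbers of peaks, 3118 with voom, 2087 with equal reads drawn and 2190 with equal reads kept. For U2AF2 it was 3298 with the number of peaks per gene. For SRSF1 it was 98 with quantile normalization, 29 with no filter, 125 with a peak in every library, 171 and 111 there with total reads or the block, 97 with pseudocount 5, 291 at p of 1e-05, 213 with voom and 1 with the replicate block. Replicates of the same number correlated at 0.051 or less, so they were not read as pairs. Leaving out 1 library gave 320 to 7704, 2249 to 6446 and 2 to 458 genes, for hnRNPA1, U2AF2 and SRSF1. With a peak in every library, leaving out control and then overexpression replicates in order gave 547, 616, 1514 and 1677 genes for hnRNPA1, 3131, 3192 and 3649 without overexpression replicates 1, 2 and 3 and at most 4537 for U2AF2, and 18, 196, 85, 94, 31 and 37 for SRSF1. Where 1 library was left in an arm of the hnRNPA1 comparison it was assumed to vary like the others.

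The U2AF2 overlap difference was -10.45 points at p of 1e-05, 16.974 with equal numbers of peaks, 1.662 by reads, 17.883 with equal reads drawn and 10.644 with equal reads kept, and for SRSF1 it was 12.134 and 10.524 in these last settings. The hnRNPA1 peak ratio was 0.168 at p of 1e-05, 0.271 by covered length and 0.205 by reads, and the SRSF1 ratio 1.789 by covered length and 1.724 by reads. The percent of U2AF2 sites found with overexpression was 91.98 in 3 of 3 libraries, 52.96 with equal numbers, 47.6 with equal reads drawn, 58.16 with equal reads kept and 77.61 to 93.83 leaving out a library; for SRSF1 62.9, 47.29, 26.98, 32.74 and 30.45 to 84.78. Events with higher inclusion were 45.2% without control replicate 2 and 32.9 to 45.2 leaving out each library. The interaction count was 431 with the number of peaks, 634 with the block and 570 to 1481 leaving out a library. Of list calls 0 held with an estimated correlation, with or without a peak in every library, 12 were made with a peak in every library and 17 with equal reads drawn or kept.

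In SRSF1 iCLIP these changed direction: with the number of peaks EIF4A2 -0.899, HNRNPA1 0.007, RPL13A -0.108, RPSA -0.325, SNORD32A -0.095 and U2AF2 0.286; HNRNPA1 also 0.071 with voom, 0.492 without control replicate 2 and 0.132 without overexpression replicate 1; MALAT1 -0.000 with quantile normalization; SRSF1 0.111 without overexpression replicate 1. Leaving out a library gave, for SRSF1 iCLIP, HNRNPA1 a range of -0.426 to 0.492 and, for SRSF1 iCLIP, SRSF1 a range of -0.361 to 0.111. In U2AF2 iCLIP FANCA was 0.093 with quantile normalization. In hnRNPA1 iCLIP HNRNPA1 was -0.089 with quantile normalization, -0.208 with equal numbers, -0.492 with equal reads drawn and -0.308 with equal reads kept, MALAT1 -0.365 with quantile normalization, SRSF1 -0.060 with the number of peaks, -0.270 with equal reads drawn and -0.010 with equal reads kept, and U2AF2 -0.057 with the number of peaks.

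Planned shares in Alu elements, near 3' splice sites and at cassette exons, and the credible-interval rule, were not run. Shallow SRSF1 libraries and the minimum of 6 reads limit which genes can be called.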

Other observations

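No test in this part was chosen only after the result was seen.

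CEBPE, a myeloid transcription factor gene (chromosome 14, peaks from 23586542 to 23588795), had peaks in every control library of the 3 proteins and no called peak in any overexpression library. Its control means were 290 normalised reads for hnRNPA1, 257 for U2AF2 and 127 for SRSF1. The small nucleolar RNA genes SNORD57 and SNORD38B had no called U2AF2 peak in any of 3 overexpression libraries, against 142 and 138 in control cells. LYZ, a hematopoietic marker, had 66.5 ± 27.4 normalised reads in U2AF2 control libraries and 200 ± 10.1 with overexpression. CEBPE, the snoRNA genes and LYZ were singled out after their values were seen.

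U2AF2 signal inside the span of an event was compared with the direction of its inclusion. Events with higher inclusion had a mean log2 U2AF2 change 0.455 above events with lower inclusion (permutation p = 0.277, adjusted p = 0.559), so no relation was found and none can be excluded. Across 6829 genes the control hnRNPA1 signal and the U2AF2 log2 change had a Spearman rho of -0.160, between the bounds set in advance. Across 6422 genes gene length and the U2AF2 change had a rho of -0.031, which argues against length as the cause. Genes are not independent replicates in either relation.

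The 10 splits of 6 libraries are too few for a share under 0.05. For U2AF2, 1 of 10 splits gave as many genes (5656, highest other 0) and 1 gave as many lists (13, highest other 10). For SRSF1, 1 gave as many genes (466, highest other 1). Adjusted within SRSF1, the real split gave 2 lists, 8 of 10 splits gave as many, and the highest other gave 7. No test was run on what gives the list calls in those splits.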
